A study of Mus musculus with 6 samples.

How the data were processed

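Expression was measured on 6 Affymetrix arrays of mouse embryonic fibroblasts under reprogramming, 1 array for each of 2 factor combinations, O(WT)SK and O(5R)SK, on days 3, 5 and 7. Groups and days were taken from the sample labels. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was hybridised. The deposited values are intensities on a linear scale, 1 per probe set and array, made by the authors with affy, per the submitters' processing notes. The version of affy, the summary method and the background correction are not given in the sources used here. The values themselves show that the 2% trimmed mean is 500 on every array and that quantiles differ between arrays, so the arrays had been scaled but not quantile normalized. The number of arrays limits the precision: there is no replicate on any day, and nothing says whether the days or combinations came from separate cultures. The p-values of single genes therefore measure only the spread between these arrays, which may be technical. Those of camera at a preset correlation set the genes of a list against all other genes. They reflect scatter between genes and are not evidence from replicate arrays.

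Of 45101 probe sets, 34958 name 1 gene in the annotation of the platform, 932 name several and 9211 none, and no gene was named from a probe set with several. Of the probe sets with 1 gene, 34754 were found in a table of RefSeq genes (GRCm38.p6), which changed 0 symbols. The array build is not named and no coordinates are given. The 64 control probe sets were kept out of the tests. There were 0 unused columns of per-sample values. For the 9012 genes with several probe sets the probe set with the highest mean over the arrays was used, which gave 18194 genes. Values were taken as log2(intensity + 16), so fold changes are on that scale and understate those of dim genes. Genes were tested if their mean lay above the 40th percentile of all probe set means (log2 5.63, an intensity of 33.5), which left 12623 genes.

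Tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 and version 1.17.8 of data.table, and Benjamini-Hochberg adjusted p-values with a threshold of 0.05. Differences between the factor combinations and between day 7 and day 3 came from 1 fit with factor combination and day (3 levels) as terms. This fit has 4 coefficients and 2 residual degrees of freedom, to which eBayes added a prior of 2.6, and its residual holds array noise as well as any real change of the factor difference with day. The difference of slopes came from a fit of factor combination by day as a number, also with 2 residual degrees of freedom, and is given per 4 days. Differences on single days and changes within a factor combination rest on 1 array per side and are given as values without a test. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

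The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 33 lists hold 691 genes, of which 642 are on the array and 506 were tested, and 32 lists had at least 3 tested genes. They cover pluripotency, epithelial, mesenchymal and fibroblast genes, contractile and cell cycle genes, stress, signalling and metabolic programs, ribosomal protein genes, and markers of other cell types that a fibroblast culture could hold or turn into. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, and adjusted over the lists of a contrast. On single days, a list's median was placed among 10000 random lists of the same size matched in 20 bins of mean expression.

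Named genes follow a rule of size. For each tested contrast the 10 largest positive and 10 largest negative differences among genes past the threshold were eligible, for the factor comparison only with the same sign on all 3 days. Where fewer passed, the largest differences not past it filled the number, with the same sign on all 3 days or, for day 7 against day 3, in both combinations. Predicted genes were skipped. Pou5f1, Sox2, Klf4 and Myc were added, and the 4 members with the largest difference from each list past the threshold and, in any case, from the pluripotency, epithelial, mesenchymal and fibroblast lists. Prom1, Myh1, Stc1 and Tenm1, the further members Dsp, Krt8, St14, Fgf4, Klf2 and Klf5 of called or described lists, and all genes named only in the closing part were chosen after their values were seen.

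The fits were tested on simulated data in 5 runs with 200 changed genes each. Log2 differences of 1, 2 and 4 were mixed within each run. Each of the 12623 genes kept its real mean, and its variance was drawn at random from the prior fitted by eBayes, without regard to that mean. The shares below therefore hold where limma's own model of the variances holds. The larger changes in a run ease the adjusted threshold for the smaller ones. The shares thus do not show how many 2-fold changes would be found where few larger ones exist. At a log2 difference of 1, 73.1% of changed genes were recovered for the factor comparison, 44.5% for day 7 against day 3 and 0.3% for the slope difference. At a log2 difference of 2 the shares were 96.1%, 89.9% and 18.5%, and at 4 they were 99.7%, 98.5% and 84.8%. Unchanged genes called per run numbered 8.2, 8.4 and 3 for the same comparisons, and 4.97%, 5.02% and 4.96% of them had an unadjusted p under 0.05. Of 32 simulated lists of 20 genes, 1 shifted by a log2 value of 0.5 was called by camera in 5 of 5 runs for each comparison with 0 other lists called, by camera with an estimated correlation in 0 of 5, and by fry in 1, 3 and 1 of 5 runs. An estimated correlation therefore had no power in this design at that shift. In the real data it called 0 of 32 lists for each comparison, so a call lost with it does not decide for or against a list. Among unshifted simulated lists, 5 of 155 medians fell outside percentiles 5 to 95. Simulated genes were drawn independently, so these runs do not show how often the preset correlation calls an unchanged list of correlated genes. Estimates for most called lists lay above the preset. They were 0.28 for adipocyte genes between the combinations. From day 3 to day 7 they were 0.173 for epithelial, 0.154 for contractile and -0.08 for Wnt target genes. They were 0.025 for macrophage, 0.016 for G2 and M phase and 0.015 for S phase genes. For slopes they were 0.333 for ribosomal protein, 0.059 for interferon response and -0.011 for epithelial genes. Where genes correlate more than the preset, camera's p-values at the preset are too small.

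Alternatives were no filter on low values, a stricter filter at the 60th percentile, the mean of a gene's probe sets, each probe set on its own, quantile normalization, a shift of each array to a common median, eBayes with a trended and robust prior (for lists, camera's variance trend, since camera has no robust option), no day term, day as a number, a pseudocount of 64, and leaving out each array in turn. The pseudocount of 64 for slopes, lists, single days and changes within a combination, and the list medians on single days under other scalings, were added after the data had been seen.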

Results

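Gene expression was measured in mouse embryonic fibroblasts of the B6CBAF1/J strain during reprogramming, the conversion of a differentiated cell toward pluripotency by delivered transcription factors. The cells received SOX2 and KLF4 together with either wild-type OCT4 (the combination O(WT)SK) or an OCT4 version that the labels call 5R (the combination O(5R)SK). What 5R stands for is not given in the labels. OCT4, encoded by Pou5f1, SOX2 and KLF4 are transcription factors of the pluripotent state. The cells were kept in embryonic stem cell medium with serum and leukemia inhibitory factor, and RNA of each combination was taken on days 3, 5 and 7. Each combination and day was hybridised to 1 Affymetrix array, 6 arrays in all, so no combination had a replicate on any day. Fibroblasts without delivered factors were not analysed here. The deposited values were linear intensities whose 2% trimmed mean was 500 on every array. Across genes, log2 values of any pair of arrays correlated with r between 0.974 and 0.982, where genes are not independent replicates. The O(5R)SK day 7 array had the lowest bright end: its highest intensity was 34285 against at least 40353 on the other arrays, and its 3' Gapdh control read 17665 against 21995 to 23810. On the O(5R)SK day 3 array the 3' to 5' ratios of the added controls dap and thr were 3.33 and 4.28, against 2.00 to 2.74 and 2.35 to 2.81 on the other arrays, while its Gapdh ratio was 0.797 against 0.768 to 0.803.

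The Pou5f1 transcript was more abundant with O(5R)SK than with O(WT)SK on each of the 3 days. Its probe set read 2290, 2292 and 2741 on days 3, 5 and 7 with O(WT)SK, and 4087, 4042 and 4803 with O(5R)SK. The difference was 0.82 on the log2 scale (SD 0.013 over 3 days), or 1.76-fold, and it missed the threshold in limma (SE 0.076, adjusted p = 0.217). That call depends on the setting: over 9 alternatives that keep all arrays, limma's adjusted p ran from 0.000587 to 0.524. Klf4 was level on its brighter probe set (log2 difference 0.01, SE 0.080, adjusted p = 0.984), while its other probe set read 0.33 higher with O(5R)SK (SD 0.10 over 3 days). Myc, which was not among the delivered factors, differed by 0.15 (SE 0.087, adjusted p = 0.651). The Sox2 probe set lay near the floor on every array, at 16.5, 31.7 and 34.1 with O(WT)SK and 4.84, 21.3 and 6.83 with O(5R)SK, and Sox2 was not tested. Whether these probe sets see the delivered copies is not known from the labels.

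The comparison of O(5R)SK with O(WT)SK, matched by day, asks how the OCT4 version alters expression during reprogramming. The largest values in favour of O(5R)SK belonged in part to pluripotency genes. Tfcp2l1, a transcription factor of naive pluripotency, read 2.68, 4.95 and 87.7 over days 3, 5 and 7 with O(WT)SK and 54.8, 56.7 and 276 with O(5R)SK, a log2 difference of 1.74 (3.33-fold, SE 0.113). Fbxo15, an embryonic stem cell F-box gene, read 3.96, 28.3 and 53.4 against 37.4, 88.4 and 349 (log2 1.69, 3.21-fold, SE 0.249). L1td1, which encodes an RNA-binding protein of embryonic stem cells, read 478, 585 and 902 against 847, 1192 and 2119 (log2 1.01, SE 0.109). The O(WT)SK values of Tfcp2l1 and Fbxo15 on days 3 and 5 lie below the filter intensity of 33.5, so the size of these differences depends on the pseudocount: with 64 in place of 16 they were 0.94 for Tfcp2l1, 1.04 for Fbxo15 and 0.96 for L1td1. None of these differences passed the threshold: limma called 0 of 12623 genes, the smallest adjusted p was 0.107, and 1180 genes had an unadjusted p under 0.05 (687 higher and 493 lower with O(5R)SK) where chance gives 631.

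Other genes with a large mean difference over the days, positive on each of the 3, were Cysrt1 (log2 1.71), Ms4a4d (1.53), the neutrophil chemokine genes Cxcl5 (1.43) and Cxcl3 (1.38), Car2 (1.42), which encodes a carbonic anhydrase, Elavl2 (1.42), which encodes an RNA-binding protein, the serine protease gene Corin (1.39) and the netrin receptor gene Unc5d (1.37). At least 2-fold higher values on all 3 days were found for 10 genes, Car2, Cysrt1, Fbxo15, Ms4a4d, Myh1, Prom1, Stc1, Tenm1, Tfcp2l1 and Unc5d, and at least 2-fold lower values for 0 genes. On the lower side stood the semaphorin gene Sema6c (-1.44), the homeobox gene Hlx (-1.35), the macrophage scavenger receptor gene Marco (-1.11), Epgn (-1.06), which encodes an epidermal growth factor family ligand, the interferon-induced gene Oas2 (-1.02), the lipid droplet gene Plin4 (-1.0), Ankrd23 (-0.99), Bcas1 (-0.96), Nccrp1 (-0.95) and Gapdhs (-0.95). The sizes of these values are not settled. With a pseudocount of 64 those on the lower side ran from -0.82 for Sema6c to -0.48 for Bcas1, and on the higher side Cysrt1 read 1.05, Cxcl3 0.90 and Corin 0.86. Leaving out O(WT)SK day 7 or O(5R)SK day 7 gave -0.70 for Hlx and -0.39 for Ankrd23. Oas2 read -0.43 without O(WT)SK day 3 or O(5R)SK day 3, and leaving out O(WT)SK day 5 or O(5R)SK day 5 gave -0.47 for Bcas1, -0.62 for Nccrp1 and -0.57 for Gapdhs. The mean of probe sets gave -0.65 for Sema6c. Adjusted p-values of the genes named for this comparison lay between 0.107 and 0.984 in limma. The stricter filter on low values gave 27 calls and limma with a trended, robust prior gave 82, of which 26 and 65 were higher with O(5R)SK. Of the genes named for this comparison, 5 and 12 were among these calls. With the trended, robust prior they included Pou5f1, Tfcp2l1, Fbxo15, L1td1, Car2 and Ms4a4d. None of the genes named above on the lower side passed under any alternative.

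By gene list, adipocyte markers were lower with O(5R)SK. Of 12 listed adipocyte genes 10 are on the array and 6 were tested. All 6 tested adipocyte genes had negative values, with a median of -0.42: Pparg (-0.57), a master regulator of fat cell formation, the fatty acid transporter gene Cd36 (-0.56), Cebpa (-0.47) and the lipoprotein lipase gene Lpl (-0.37). camera put this list past its threshold (adjusted p = 0.00344), and the call was lost in fry (adjusted p = 0.362), without the filter (0.151) and with the mean of a gene's probe sets (0.0671). With an estimated correlation, which called 0 lists for any comparison, camera's adjusted p was 0.753. No adipocyte gene passed over all genes, and adjusted over the list alone 3 were lower. Macrophage and leukocyte genes, which lie on the same side, were negative for 16 of 19 (median -0.15, camera adjusted p = 0.0544), and both Cd36 and Lpl are also known in macrophages. Cebpa read -0.13 when O(WT)SK day 5 or O(5R)SK day 5 was left out and -0.79 when O(WT)SK day 3 or O(5R)SK day 3 was, and with a pseudocount of 64 Pparg read -0.36, Cd36 -0.35 and Cebpa -0.23.

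Of 31 listed pluripotency genes 29 are on the array and 13 were tested, the others on the array lying below the filter. The filter takes the mean over all arrays, so a dim gene can pass through high values in 1 combination. Of the 13 tested 10 had positive values (median 0.12, mean 0.35), and adjusted over the list alone 3 were higher, while the chromatin gene Utf1 read -0.49. Of 20 epithelial genes 15 were positive, led by Cdh1, which encodes E-cadherin (0.74, SE 0.216), Spint1 (0.54), Grhl2 (0.48) and Esrp2 (0.47), with 0 past the threshold in limma over all genes or adjusted over the list alone. The mesenchymal list was negative for 13 of 20 genes, among them Zeb1 (-0.36), a repressor of E-cadherin, Vim (-0.25), S100a4 (-0.25) and Zeb2 (-0.23). Of 25 fibroblast and collagen genes 19 were negative, such as Col1a2 (-0.44) and Col6a3 (-0.42), while Lum read 0.62 and Col12a1 0.41. camera did not call these lists, with adjusted p-values of 0.0544 for pluripotency and for fibroblast genes, 0.144 for epithelial and 0.286 for mesenchymal genes. These calls hang on the setting. Without O(WT)SK day 3 or O(5R)SK day 3 the pluripotency (0.0476), fibroblast (median -0.16, 0.0475) and epithelial lists (median 0.21, 0.0273) passed. The variance trend called the pluripotency and fibroblast lists (0.00773 each), a common median the pluripotency list (0.0194), and the stricter filter (0.00871) and a pseudocount of 64 (0.0414) the fibroblast list. The pluripotency median was 0.04 without the filter, 0.03 with the mean of probe sets, and 0.20 without O(WT)SK day 5 or O(5R)SK day 5. Single genes of these lists rest on few values. Leaving out O(WT)SK day 5 or O(5R)SK day 5 gave -0.13 for Grhl2, whose differences on days 3, 5 and 7 were 0.06, 1.72 and -0.33, and -0.16 for Utf1. Leaving out O(WT)SK day 7 or O(5R)SK day 7 gave 0.44 for Cdh1, 0.27 for Spint1, 0.20 for Esrp2, -0.20 for Zeb1, -0.12 for Vim, -0.15 for S100a4, -0.14 for Zeb2 and 0.16 for Col12a1. With the mean of probe sets Zeb1 and Zeb2 turned to 0.05 and 0.07, Vim read -0.04 and Col12a1 0.17.

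**Figure D1:**
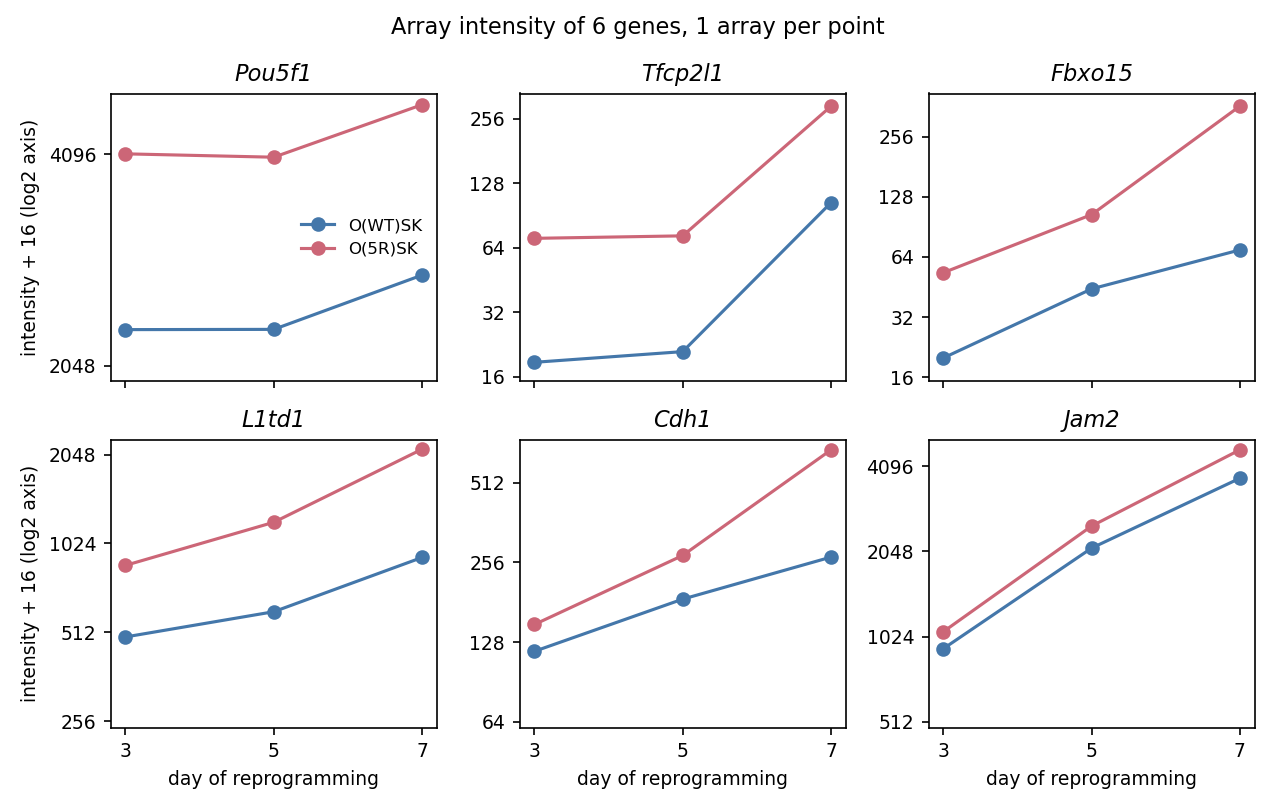
Intensity plus 16 on a log2 axis against the day of reprogramming for Pou5f1, Tfcp2l1, Fbxo15, L1td1, Cdh1 and Jam2, with 1 array per point, O(WT)SK in blue and O(5R)SK in red. On each of the 3 days the O(5R)SK point lies above the O(WT)SK point in all 6 panels, by 0.82 on average for Pou5f1 and by 1.74 for Tfcp2l1 on the log2 scale.

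On single days the distance between the factor combinations was widest on day 7. At least 2-fold higher values with O(5R)SK were found for 87 genes on day 3, 126 on day 5 and 218 on day 7, and at least 2-fold lower values for 80, 86 and 49 genes. After quantile normalization 93, 126 and 175 genes were higher and 80, 84 and 68 lower. All these counts rest on 1 array per combination and have no replicate check. The day differences correlated weakly across genes, with r = 0.136 between days 3 and 5, 0.097 between days 3 and 7 and 0.231 between days 5 and 7, and genes are not independent replicates. The same sign on all 3 days was seen for 4262 genes (33.8%, where chance gives 25%), 2001 of them higher and 2261 lower with O(5R)SK.

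The 13 tested pluripotency genes, of 31 listed, had a positive median on every day, 0.20, 0.19 and 0.33 on days 3, 5 and 7, at percentiles 98.3, 97.4 and 98.7 of 10000 random lists matched on expression. Epithelial genes went from -0.02 on day 3 (percentile 39.0) to 0.11 on day 5 (92.3) and 0.42 on day 7 (99.9). S phase genes read 0.04, 0.04 and 0.12 (percentiles 87.3, 91.1 and 99.6). Negative medians were found for fibroblast and collagen genes (-0.04, -0.09 and -0.20, percentiles 1.8, 3.7 and 2.5), for adipocyte genes (-0.17, -0.42 and -0.60, percentiles 12.5, 0.9 and 0) and, on days 5 and 7, for macrophage and leukocyte genes (-0.23 and -0.19, percentiles 0 and 0.2). Interferon response genes went the other way over time, from -0.29 on day 3 (percentile 0) through -0.08 (14.6) to 0.09 on day 7 (67.5), where the day 3 value rests on the O(5R)SK day 3 array with its high dap and thr ratios, and whether these bear on it was not tested. Ribosomal protein genes read 0.03, -0.11 and -0.26 (percentiles 72.9, 4.3 and 3.6), and on day 7 the matched random lists themselves had a median of -0.16. Shifting the arrays to a common median moved the day 7 difference of the median gene from -0.02 to -0.14. Relative to that shift the day 7 medians were 0.35 for pluripotency, 0.44 for epithelial, 0.14 for S phase, 0.11 for interferon response, -0.19 for fibroblast, -0.17 for macrophage, -0.59 for adipocyte and -0.24 for ribosomal protein genes. Such a shift moves all genes alike and leaves a compressed bright end as it is. After quantile normalization the medians were, in the same order, 0.30, 0.37, 0.10, 0.01, -0.12, -0.20, -0.66 and 0.01. The fibroblast and interferon values thus also depend on the scaling.

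**Figure D2:**
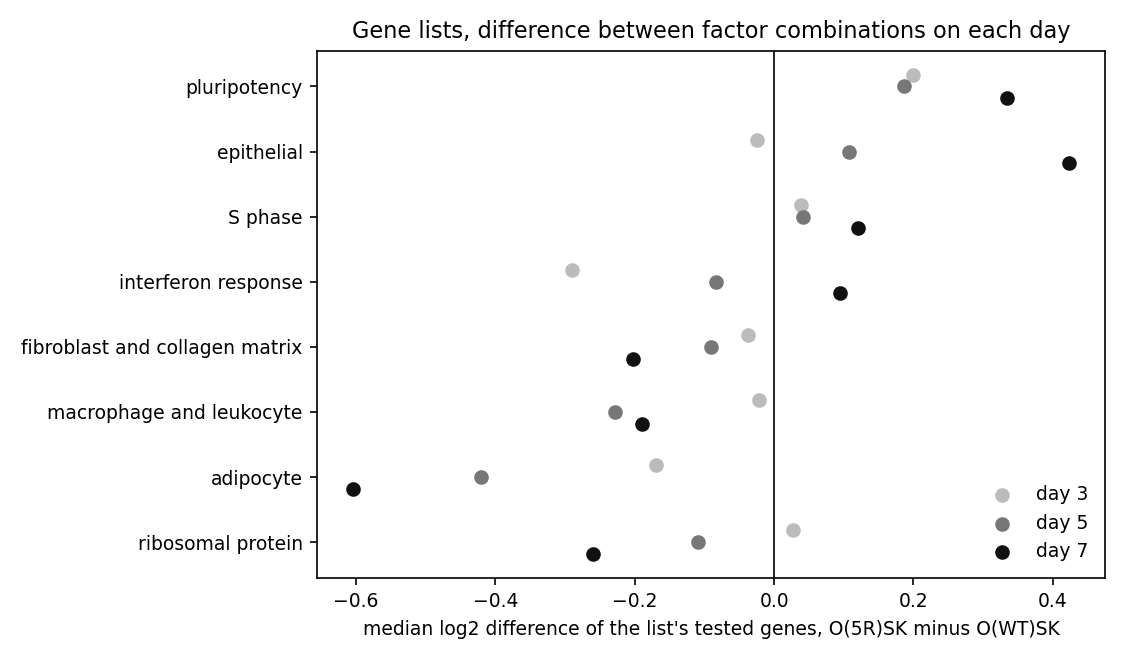
Median log2 difference, O(5R)SK minus O(WT)SK, of the tested genes of 8 lists on days 3, 5 and 7 (light to dark points), from 1 array per combination and day. The epithelial median goes from -0.02 to 0.42 and the interferon median from -0.29 to 0.09, while the pluripotency median stays above 0 and the adipocyte median below 0. The ribosomal protein median, -0.26 on day 7, becomes 0.01 after quantile normalization. With a common median of the arrays, which shifts all genes, the day 7 interferon median is -0.03, or 0.11 relative to the median gene. After quantile normalization the day 7 interferon median is 0.01 and the fibroblast median -0.12.

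The comparison of day 7 with day 3, over both factor combinations, describes the course of reprogramming that they share. Pluripotency genes such as Fbxo15 (log2 2.29, 4.88-fold, SE 0.305), Tfcp2l1 (2.26, 4.79-fold, SE 0.138) and Jam2 (2.07, 4.20-fold, SE 0.098) rose, and so did the epithelial genes Cdh1 (1.69, 3.22-fold, SE 0.265) and Ehf (1.89, 3.70-fold, SE 0.261). Smooth muscle and contractile genes fell, led by the leiomodin gene Lmod1 (-2.10, SE 0.122), as did macrophage genes such as the lysozyme gene Lyz2 (-1.58, SE 0.096) and, among mesenchymal genes, the transforming growth factor gene Tgfb3 (-1.99, SE 0.119). With a pseudocount of 64 the values of Fbxo15 and Tfcp2l1, dim on day 3, were 1.41 and 1.35 and that of Ehf was 1.16, and with the mean of probe sets Ehf read 0.99 and Jam2 1.30. In limma 1287 of 12623 genes passed an adjusted p of 0.05, 823 higher and 464 lower on day 7, of which 319 and 135 changed at least 2-fold. The smallest adjusted p was 0.00765. With any day 3 or day 7 array left out limma called 0 genes, and 1073 without either day 5 array, and without the filter on low values it also called 0. After shifting arrays to a common median, 578 of 1171 called genes were higher.

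With the pseudocount of 16 the largest rises were those of Egfl6 (3.56, 11.8-fold, SE 0.526, adjusted p = 0.0284), Ms4a4d (3.52, 11.4-fold, SE 0.207, adjusted p = 0.00765), the steroid-metabolising aldo-keto reductase gene Akr1c14 (3.27), the lipopolysaccharide-binding protein gene Lbp (3.09), the protease inhibitor gene Serpinb1a (3.04), the thyrotropin-releasing hormone gene Trh (3.01), Fxyd6 (3.00), Elobl (2.80), the ferritin receptor gene Scara5 (2.80) and Sptssb (2.75), which encodes a subunit of the enzyme that starts sphingolipid synthesis. The largest falls were those of the chemokine gene Ccl5 (-2.78, SE 0.266, adjusted p = 0.0141), the macrophage receptor genes Marco (-2.51) and Clec4d (-2.45), Ifi27l2b (-2.40), the sialic acid receptor gene Siglecg (-2.33), Pmch (-2.28), which encodes the precursor of melanin-concentrating hormone, Sprr2k (-2.15), the fatty acid transporter gene Cd36 (-2.11), Lmod1 (-2.10) and Gpr149 (-2.04). All of them passed the threshold, with adjusted p-values from 0.00765 to 0.0284, but sizes and order depend on the pseudocount. With 64 Akr1c14 read 3.19, Ms4a4d 2.98, Egfl6, whose O(5R)SK day 3 intensity was 15.2, 2.61, Lbp 2.15, Ccl5 -1.64 and Marco -1.38. With the mean of probe sets Lbp read 1.76, Scara5 1.55 and Cd36 -1.31.

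Among the pluripotency genes 6 of 13 rose and 2 fell, over all genes as well as adjusted over the list alone. Utf1 (1.78), the fibroblast growth factor gene Fgf4 (1.63) and L1td1 (1.10) rose, while Klf2 (-1.11) and Klf5 (-0.83) fell. Utf1, at 7.52 and 11.4 on day 3, read 0.88 with a pseudocount of 64 and missed the threshold after quantile normalization (adjusted p = 0.053). The list as a whole was not called by camera (adjusted p = 0.155), though it was with a common median (0.0208) and in fry (0.0193). Its median, 0.68, was 0.01 with the stricter filter, 0.30 without a filter, 0.20 with the mean of probe sets, 1.15 without O(WT)SK day 7 and 0.33 without O(5R)SK day 7. Epithelial genes were called higher (median 0.46, adjusted p = 0.0294, and adjusted p = 0.588 with an estimated correlation). Of 20 epithelial genes 7 rose and 1 fell, or 8 and 1 adjusted over the list alone. The desmosome gene Dsp (1.09), Krt8 (1.18) and St14 (1.17) were among those that rose, Krt19 (-1.38), a keratin of simple epithelia, fell, and Cldn3 read 1.84 (adjusted p = 0.0504), which became 0.99 with a pseudocount of 64 (adjusted p = 0.0194), 1.22 without O(5R)SK day 7 and a call without O(WT)SK day 5 or O(5R)SK day 5 (adjusted p = 0.0268). The epithelial median was 0.89 with the stricter filter, 0.29 with a pseudocount of 64, 0.79 without O(WT)SK day 3 and 0.86 without O(WT)SK day 7. The epithelial call was lost without O(5R)SK day 3 (adjusted p = 0.222), without O(5R)SK day 7 (0.134), with the stricter filter (0.129) and in fry (0.0790). Wnt target genes were called higher (median 0.29, adjusted p = 0.0172, and adjusted p = 0.567 with an estimated correlation), with Lgr5 (1.60), Axin2 (0.97) and Nkd2 (0.57) rising among 10 tested and 4 adjusted over the list alone, while Ccnd1 read 0.46. With the mean of probe sets Lgr5 read 1.03, and the calls of Axin2 (0.16, adjusted p = 0.409) and Nkd2 (0.40, adjusted p = 0.242) were lost, as they were after quantile normalization (adjusted p = 0.0612 and 0.0808). Nkd2 also lost its call with a common median (0.0853), the trended and robust prior (0.0664), day as a number (0.177) and without O(WT)SK day 5 or O(5R)SK day 5 (0.0689). Without O(5R)SK day 3 or day 7 the adjusted p of the Wnt list was 0.0511 and 0.0599, and it was 0.137 with the stricter filter, 0.0866 with the mean of probe sets and 0.0614 with the variance trend.

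All 16 contractile genes had lower values on day 7 (median -0.61, camera adjusted p = 4.53e-09, and adjusted p = 0.515 with an estimated correlation), and 9 fell, or 13 adjusted over the list alone, among them Tagln2 (-1.17), the smooth muscle myosin gene Myh11 (-1.16) and the calponin gene Cnn1 (-1.06). Cell cycle genes went down as well. Of 27 G2 and M phase genes 9 fell, or 19 adjusted over the list alone (median -0.43, adjusted p = 4.53e-09, and adjusted p = 0.334 with an estimated correlation), with Cenpe (-0.90), Anln (-0.89), Aurka (-0.77) and Tpx2 (-0.74), genes of the mitotic spindle and of cytokinesis. Of 24 S phase genes 6 fell, or 16 adjusted over the list alone (median -0.39, adjusted p = 7.39e-09, and adjusted p = 0.334 with an estimated correlation), among them the cyclin gene Ccne1 (-1.0), Cdc6 (-0.95) and the primase gene Prim1 (-0.76), while Ccne2 read -0.64 (adjusted p = 0.0899), or -0.37 without O(WT)SK day 3. Markers of macrophages and leukocytes moved with them: 10 of 19 fell, or 13 adjusted over the list alone (median -0.90, adjusted p = 7.39e-09, and adjusted p = 0.334 with an estimated correlation), including Cd52 (-1.64), Tyrobp (-1.46) and Adgre1 (-1.23). With the mean of probe sets the calls of Myh11 (-0.60, adjusted p = 0.117), Prim1 (-0.63, 0.118), Cenpe (-0.70, 0.0821), Aurka (-0.17, 0.644) and Tpx2 (-0.33, 0.144) were lost, and Anln read -0.54. In fry, which does not compare with other genes, the adjusted p was 0.0193 for contractile and 0.0204 for G2 and M phase genes. It was 0.0165 for S phase genes and for macrophage and leukocyte genes.

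The fibroblast and mesenchymal lists were not called. Of 25 fibroblast and collagen genes 4 fell and 0 rose in limma, over all genes as well as adjusted over the list alone, including Serpinf1 (-0.96), the fibroblast surface marker gene Thy1 (-0.71) and the periostin gene Postn (-0.66), and Col12a1 read -0.58 (adjusted p = 0.176), or -0.16 with the mean of probe sets, -0.28 without O(WT)SK day 3, -0.21 without O(WT)SK day 7, -0.87 without O(5R)SK day 3 and -0.94 without O(5R)SK day 7. The median of that list was 0.10 and its mean -0.03, with camera's direction down (adjusted p = 0.747). That median turned to -0.04 without O(WT)SK day 3 and -0.09 without O(WT)SK day 7. It was -0.01 with a common median, which shifts all genes. This scaling moved the change of the median gene from 0.03 to -0.01 with O(WT)SK and from 0.03 to -0.14 with O(5R)SK. Of 20 mesenchymal genes 2 fell, also adjusted over the list alone, Tgfb3 and Foxc2 (-0.52), while Snai1 read -0.47 and Prrx1 0.39 (camera adjusted p = 0.289). Without O(WT)SK day 5 or O(5R)SK day 5 the calls of Foxc2 (adjusted p = 0.0864) and Postn (0.0528) were lost, as was that of Foxc2 with the mean of probe sets (0.0523) and that of Postn with day as a number (0.133). Called lists in fry numbered 12, of which 5 were called by camera too, and with an estimated correlation camera called 0 of 32 lists, where it had called 6 with the preset one.

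**Figure D3:**
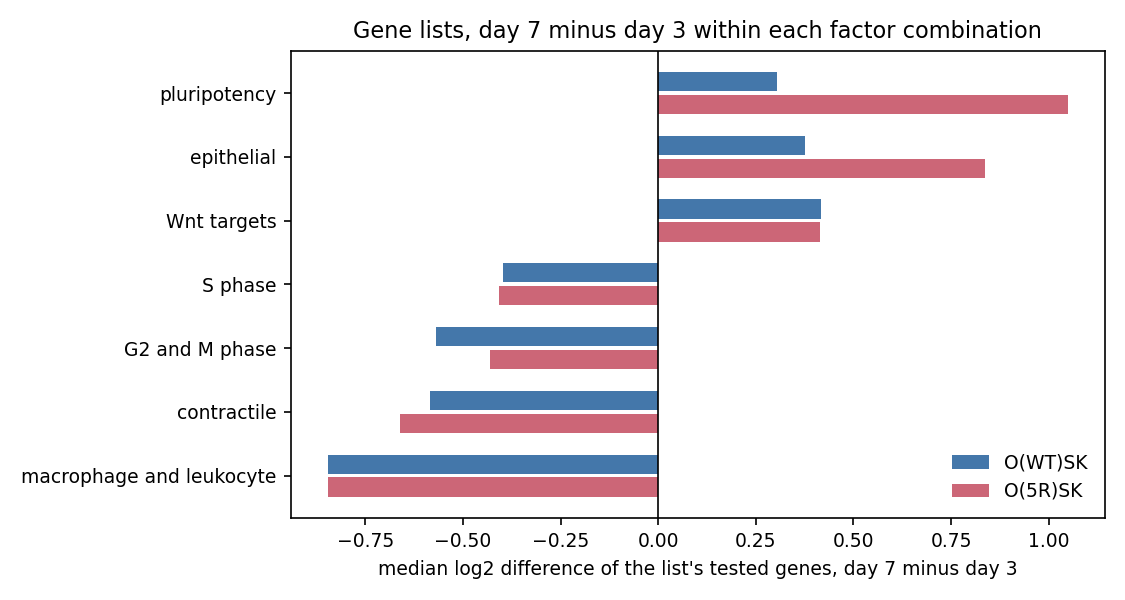
Median log2 difference between day 7 and day 3 of the tested genes of 7 lists, with O(WT)SK in blue and O(5R)SK in red, from 1 array per combination and day. The pluripotency bars stand at 0.30 and 1.05 and the epithelial bars at 0.38 and 0.84, while the bars of the S phase, G2 and M phase, contractile and macrophage lists lie below 0 in both combinations. The difference of slopes of the pluripotency list had a median of 0.14 and was not called (camera adjusted p = 0.686).

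Within each factor combination, the change from day 3 was larger on day 7 than on day 5. With O(WT)SK 164 genes were at least 2-fold higher and 101 lower on day 5, and 446 and 239 on day 7. With O(5R)SK the counts were 191 and 123 on day 5 and 551 and 201 on day 7. After quantile normalization the day 7 counts were 403 higher and 265 lower with O(WT)SK. They were 418 and 256 with O(5R)SK, so the combinations were close under that scaling. Both combinations shared 254 genes at least 2-fold higher on day 7, where independent lists would share 19.5, and 99 at least 2-fold lower, where independent lists would share 3.8. The changes from day 3 to day 7 correlated across genes with r = 0.607, and 8 genes were 2-fold apart in opposite directions. The pluripotency median on day 7 was 0.30 with O(WT)SK (percentile 95.1) and 1.05 with O(5R)SK (percentile 100), and the epithelial median 0.38 (99.3) and 0.84 (100). For the pluripotency list the tested difference of slopes was smaller than these medians are apart, with a median of 0.14 and 8 of 13 positive, and camera did not call it (adjusted p = 0.686, and 0.981 with an estimated correlation). That median was 0.50 without O(WT)SK day 3, 0.38 without O(WT)SK day 7, 0.23 without O(5R)SK day 3, 0.08 without O(5R)SK day 7 and 0.01 with a common median or the mean of probe sets. Macrophage genes had medians of -0.85 in both, contractile genes -0.58 and -0.66, S phase genes -0.40 and -0.41 and G2 and M phase genes -0.57 and -0.43, each at percentile 0. Fibroblast and collagen genes stood at 0.17 with O(WT)SK (percentile 99.4) and at -0.08 with O(5R)SK (65.9), where quantile normalization turned the O(5R)SK median to 0.07. Shifting arrays to a common median moved the O(5R)SK change of the median gene from 0.03 to -0.14, and relative to that shift the O(5R)SK medians were 1.02 for pluripotency and 0.81 for epithelial genes. After quantile normalization these O(5R)SK medians were 0.89 and 0.75.

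Whether the factor combinations parted over time was tested as the difference of their slopes over days, given here as the log2 change over 4 days. Epithelial genes climbed more steeply with O(5R)SK: 15 of 20 slope differences were positive, with a median of 0.38 (camera adjusted p = 0.0119, and adjusted p = 0.946 with an estimated correlation). Cdh1 went from 102 to 252 with O(WT)SK and from 133 to 665 with O(5R)SK (slope difference 1.01, SE 0.250), Ehf from 23.5 to 85.9 and from 21.7 to 184 (1.04, SE 0.171), and Cldn3 read 1.50 and Elf3 1.42. These rest on single arrays in part: without O(5R)SK day 3 Elf3 read 0.10, without O(WT)SK day 7 Cldn3 read 0.88, and without O(5R)SK day 7 Cdh1 read 0.55 and Elf3 2.75. Interferon response genes also had higher slopes with O(5R)SK, 19 of 22 positive with a median of 0.38 (camera adjusted p = 0.00144, and adjusted p = 0.946 with an estimated correlation), led by Ifit3 (1.13), Cxcl10 (1.02), Oas1a (0.95) and Usp18 (0.89). Without O(WT)SK day 7 Cxcl10 read 0.50 and Oas1a 1.63. Without O(WT)SK day 3 Oas1a read 0.27, Cxcl10 1.54 and Usp18 0.52. Without O(5R)SK day 3 Usp18 read 0.35 and Oas1a 1.55, and without O(5R)SK day 7 Cxcl10 read 0.54, Oas1a 0.35 and Usp18 1.44. Ribosomal protein genes had lower ones, 15 of 17 negative with a median of -0.27 (camera adjusted p = 0.00413, and adjusted p = 0.946 with an estimated correlation). Among them Rplp0 read -0.54, Rps2 -0.48 and Rpl19 -0.45, while Rpl37 read 0.61, and after quantile normalization the list's median was 0.011. The epithelial median was 0.71 without O(WT)SK day 3, 0.23 without O(5R)SK day 7 and 0.25 with a common median. The interferon median was 0.75 without O(WT)SK day 7 and 0.23 without O(WT)SK day 3, and the ribosomal median -0.14 with the mean of probe sets. In these lists 0 genes passed in limma, over all genes or adjusted over each list alone.

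For single genes limma called 0 slope differences among 12623, with 949 at an unadjusted p under 0.05 (621 higher and 328 lower with O(5R)SK, where chance gives 631) and a smallest adjusted p of 0.648. The largest values, such as those of Pidd1 (3.28), C2cd4b (3.28), Ttc38 (2.80), Sobp (2.75), the T cell receptor complex gene Cd3g (2.55), Gstm3 (2.32) and Oosp3 (2.32) on the one side and Tmc8 (-3.69), the recombination gene Rad51c (-2.66), Sardh (-2.61), Hlx (-2.52), Slc5a10 (-2.48) and Dnase1l2 (-2.43) on the other, came from genes of low intensity, with no array above 189 for any of them. Leaving out 1 array moved several by far, such as Slc5a10 to -0.05 without O(5R)SK day 7 and Pidd1 to 0.31 and Ttc38 to 0.21 without O(5R)SK day 3. Among pluripotency genes Fbxo15 read 0.98, Dppa5a 0.91, Esrrb 0.75 and Utf1 -0.77, mesenchymal genes included Vim (-0.48), Zeb1 (-0.47), Zeb2 (-0.46) and Sparc (-0.43), and fibroblast genes included Eln (-1.03), Col12a1 (0.88), Col3a1 (-0.73) and Pdgfra (0.36), none past the threshold. Without O(5R)SK day 7 Fbxo15 read 0.14, Eln -0.19, Col12a1 0.22, Vim -0.25 and Dppa5a 1.58. Without O(5R)SK day 3 Dppa5a read 0.23, Fbxo15 1.82, Eln -1.88 and Col12a1 1.54. Without O(WT)SK day 7 Col3a1 read -0.32, Eln -0.23, Dppa5a 0.38 and Fbxo15 0.48. Without O(WT)SK day 3 Col3a1 read -1.14, Eln -1.84, Col12a1 0.51, Dppa5a 1.43 and Fbxo15 1.48. Leaving out 1 array turned the sign of Utf1 (0.73) and Zeb2 (0.20) without O(WT)SK day 3, of Esrrb (-0.48) and Pdgfra (-0.21) without O(WT)SK day 7 and of Zeb1 (0.28) without O(5R)SK day 7, and with the mean of probe sets Esrrb read -0.60, Zeb1 0.17 and Zeb2 0.63. Slopes of Pou5f1 (-0.03), Klf4 (0.04) and Myc (-0.12) were close between the combinations. Without the O(5R)SK day 7 array camera called 0 of the 3 lists, with adjusted p-values of 0.340 for epithelial, 0.340 for interferon and 0.357 for ribosomal protein genes. Without the O(WT)SK day 3 array they were 0.0882, 0.442 and 0.292, and the epithelial call was also lost without O(WT)SK day 7 (0.118), without O(5R)SK day 3 (0.050) with the stricter filter (0.220), without a filter (0.0503) and with the mean of probe sets (0.0986). The ribosomal protein call was lost with the mean of probe sets (0.316).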

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

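Of the tests in this part, the one on the hybridisation controls was chosen only after the result had been seen.

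Epithelial genes differed between the factor combinations in their slopes over days, by a median of 0.38 (camera adjusted p = 0.0119). That test of the difference itself is what set the list apart, and over its 9 alternatives the adjusted p ran from 0.00197 to 0.946. The call was lost without O(5R)SK day 7 (0.340), O(WT)SK day 7 (0.118), O(WT)SK day 3 (0.0882) or O(5R)SK day 3 (0.050). It was also lost in fry (adjusted p = 0.0925), with the stricter filter, without a filter and with the mean of probe sets. The loss with an estimated correlation (0.946) decides nothing, since that setting called 0 lists for any comparison. The estimate for this list, -0.011, lay below the preset 0.01. The median was 0.71 without O(WT)SK day 3 and 0.23 without O(5R)SK day 7. Interferon response genes differed in the same way, by a median of 0.38 (camera adjusted p = 0.00144, from 0.000214 to 0.946 over the alternatives), from the lowest percentile, 0, on day 3 to 67.5 on day 7. The interferon call was lost without O(WT)SK day 3 (0.442) or O(5R)SK day 7 (0.340), in fry (adjusted p = 0.484) and with an estimated correlation (0.946), where no list was called. Its median was 0.23 without O(WT)SK day 3 and 0.75 without O(WT)SK day 7. The correlation estimate for the interferon list, 0.059, lay above the preset.

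Ribosomal protein genes had lower slopes with O(5R)SK, by a median of -0.27 (camera adjusted p = 0.00413, from 1.95e-06 to 0.946 over the alternatives). The call was lost without O(WT)SK day 3 (0.292) or O(5R)SK day 7 (0.357), in fry (adjusted p = 0.363) and with the mean of probe sets. It was also lost with an estimated correlation (0.946), where no list was called. The estimate for this list, 0.333, lay above the preset 0.01. After quantile normalization the median was 0.011, which is what a compressed bright end of the O(5R)SK day 7 array would give, so that explanation may account for the pattern, although quantile normalization equalises bright ranks by construction and could also remove a real change of so bright a group. The 4 brightest added cre controls, which carry no cellular RNA, read -0.18 on that array relative to the mean of the others, against -0.03 to 0.10 on the other arrays. This lies between the bounds of that test, which were also written after the result had been seen, and leaves the explanation open. A real difference between the OCT4 versions in ribosomal protein transcripts was not tested apart from these.

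A probe set that the comparisons do not use, the control AFFX-MUR_b2_at, read higher on all O(5R)SK arrays (1114, 1031 and 1046) than on all O(WT)SK arrays (813, 727 and 772), by 0.46 on the log2 scale. Of 58 control probe sets above the filter, 2 had all O(5R)SK arrays above and 11 all O(5R)SK arrays below the others, where chance sets 10% apart in either direction (5.8 probe sets). The 11 include several probe sets each of the bright actin, Gapdh and 18S RNA, so they are not independent. The 3' 18S set read 19823, 17809 and 14303 on days 3, 5 and 7 with O(5R)SK and 22310, 20838 and 22082 with O(WT)SK. Its lower values are thus not confined to day 7. Whether this bears on the ribosomal protein list was not tested. No group held enough arrays for a test of a single array against its group.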

How the results depend on the processing

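Genes called between the factor combinations, 0 with limma, numbered 27 with the stricter filter, 82 with the trended and robust prior, 3 with day as a number and 2 with a pseudocount of 64. The other alternatives gave 0, and leaving out any array gave 0 to 0. Genes called between day 7 and day 3, 1287, numbered 0 without the filter, 2202 with the stricter filter, 2846 with the trended and robust prior and 1973 with a pseudocount of 64. The count stayed within 1.5 times with the mean of probe sets (883), quantile normalization (1162), a common median (1171), each probe set on its own (1088) and day as a number (1598). Leaving out an array gave 0 to 1073 (0 without any day 3 or day 7 array, 1073 without either day 5 array). Of the 49 named genes past the threshold, 46 kept it after quantile normalization, 48 with a common median, 48 with the trended and robust prior, 47 with day as a number, 49 with a pseudocount of 64, 39 of 39 with the stricter filter and 38 of 46 with the mean of probe sets, 0 without the filter and 0 without a day 3 or day 7 array. Under these alternatives 0 of them reversed. The filters, the prior and day as a number leave the difference of a gene unchanged, so a reversal was not possible there. Slope differences called, 0, numbered 2 with the trended and robust prior and 0 otherwise, and 0 to 0 with an array left out.

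Lists called between the factor combinations, 1, numbered 0 without the filter, 2 with the stricter filter, 0 with the mean of probe sets, 2 with a common median, 5 with the variance trend, 0 with an estimated correlation, 0 in fry, 2 with a pseudocount of 64 and 1 to 5 with an array left out (5 without either day 3 array, 2 without either day 7 array). Lists called between day 7 and day 3, 6, numbered 0 with an estimated correlation, 12 in fry and 4 to 9 with an array left out. Lists called for the slope, 3, numbered 1 with the mean of probe sets, 9 with the variance trend, 0 with an estimated correlation, 0 in fry, 5 with a pseudocount of 64 and 0 to 6 with an array left out (1 without O(WT)SK day 3, 5 without O(WT)SK day 7, 6 without O(5R)SK day 3 and 0 without O(5R)SK day 7). The median slope difference of the ribosomal protein list turned from -0.27 to 0.011 after quantile normalization (adjusted p = 0.822), the only reversal among the called lists, and its adjusted p ran from 1.95e-06 to 0.946 over the 9 alternatives.

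Counts of genes at least 2-fold apart on single days moved most with dim genes. Without the filter, 465, 507 and 636 genes were higher and 455, 500 and 382 lower with O(5R)SK on days 3, 5 and 7. With a pseudocount of 64 these were 12, 26 and 73 higher and 8, 6 and 10 lower. With the mean of probe sets 56, 80 and 143 were higher, and 45 on day 3 and 53 on day 5 were lower. Against day 3, without the filter, O(WT)SK had 623 higher and 442 lower on day 5 and 923 and 649 on day 7, and O(5R)SK had 597 and 490 on day 5 and 1022 and 491 on day 7. With a pseudocount of 64, O(WT)SK had 41 and 27 on day 5 and 209 and 107 on day 7, and O(5R)SK had 57 and 31 on day 5 and 275 and 116 on day 7. For all of these shifts the cause was not tested. The pseudocount of 64 for lists, slopes and the 2-fold counts was chosen after seeing the data. Signal over background may limit what dim genes can show, which was not measured here.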

Other observations

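Of the tests in this part, those of an intensity trend in the macrophage list, of the cell cycle lists and of the Pou5f1 level were chosen only after the results had been seen, as were the genes named first.

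Of 19 inflammatory and secretory genes 6 rose and 2 fell from day 3 to day 7 in limma, or 11 and 4 adjusted over the list alone: Ccl20 (1.75), Saa3 (1.73), Il6 (1.50) and Ccl2 (1.26) rose, while Csf1 (-1.49), the growth factor of macrophages, fell with Ccl5. Of 20 p53 target and senescence genes 5 rose and 0 fell, also adjusted over the list alone, including Cdkn2a (1.52) and Cdkn2b (1.05), whose products block the cell cycle kinases, Perp (0.78) and Trp53inp1 (0.75). camera called neither list (adjusted p = 0.155 for both), while fry, which does not compare with other genes, called both (adjusted p = 0.0193 and 0.0133). Among BMP targets the BMP antagonist gene Grem1 (1.37) rose and Bambi (-0.68) fell, and of the chromatin genes 1 of 33 passed, Tet2 (0.86), which encodes an enzyme that oxidises methylated DNA. Hoxc8 (0.59) was the single one of 19 Hox genes past the threshold, where 5 rose adjusted over the list alone (fry adjusted p = 0.0385). TGF-beta targets had a median of -0.25 (camera adjusted p = 0.155, fry 0.0172), with 2 genes rising and 1 falling of 12, or 2 and 3 adjusted over the list alone. Medians were -0.16 for glycolysis, -0.01 for oxidative phosphorylation, 0.01 for unfolded protein and amino acid stress, -0.17 for heat shock, -0.15 for immediate early and -0.15 for ribosomal protein genes, none called by camera or fry. The 4 tested sex-linked genes had a median of 0.13 between the factor combinations (camera adjusted p = 0.243). By day this median was -0.09, 0.13 and 0.33 on days 3, 5 and 7. Their slope differences were all positive, with a median of 0.43 (camera adjusted p = 0.0559).

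From day 3 to day 7 the keratinocyte genes Sprr1a (1.82) and Ivl (1.32) rose, as did Col2a1 (1.20) of cartilage, Robo4 (1.82) and Eng (0.55) of endothelium and Lama1 (1.04), Thbd (0.70) and Dab2 (0.61) of extraembryonic endoderm. Median changes were 0.25 for keratinocyte, 0.25 for cartilage and bone, 0.20 for endothelial, 0.10 for extraembryonic endoderm, 0.11 for trophoblast, 0.26 for primitive streak and mesoderm, 0.00 for neural and -0.02 for muscle genes, and camera called none of these lists for any of the 3 comparisons. For day 7 against day 3 fry called the keratinocyte list (adjusted p = 0.021) and the primitive streak and mesoderm list (adjusted p = 0.0406). The germline list had 2 tested genes and was not tested. Alpl, which encodes the alkaline phosphatase used as an early reprogramming marker, read 23.8, 33.6 and 32.2 with O(WT)SK and 48.8, 97.6 and 128 with O(5R)SK (log2 1.16, adjusted p = 0.296). Prom1 read 738, 861 and 1165 against 2013, 2174 and 2816 (log2 1.34, adjusted p = 0.107).

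The fall of macrophage and leukocyte genes from day 3 to day 7 led to the hypothesis that the cultures held fewer macrophages on day 7. In a second list of 30 macrophage genes, written down before its values were seen and holding 0 genes of the fibroblast lists, 92% of the 25 tested genes lay below 0, 12 fell and 0 rose in limma, and the median was -0.87 against -0.90 in the first list, which is consistent with that hypothesis. Lyz2, of the first list, went from 6294 to 2172 with O(WT)SK and from 5824 to 1874 with O(5R)SK, while Ctsc, of the second list, read 0.55 (adjusted p = 0.0648). A trend with intensity as the whole source is argued against, because the first list's median lay at percentile 0 of matched random lists in both combinations. How many of the genes fibroblasts themselves express was not tested, the labels name no sort that would remove macrophages, and lower expression per macrophage stays open.

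For the differences between the factor combinations on day 7, the hypothesis that O(5R)SK cells were simply further along the shared course was tested on arrays not shared between both sides. Across genes, O(5R)SK minus O(WT)SK on day 7 correlated with the change from day 3 to day 5 in O(WT)SK at r = 0.007 (0.003 after quantile normalization), where the same change correlated at r = 0.256 with that of O(5R)SK from day 5 to day 7. This argues against a lead as large as that from day 5 to day 7. The r of a smaller lead was not computed, so a smaller one stays open. Of the 6 lists called over time 3 moved the same way: epithelial, contractile and macrophage genes. The others were the Wnt list, at -0.01, and both cell cycle lists. The cell cycle lists fell over the course, so a uniform shift would put them lower with O(5R)SK on day 7, and neither was. S phase genes had a median of 0.12 (percentile 99.6). G2 and M phase genes had 0.02 (percentile 80.2), within the spread of random lists. A common median moved the latter to -0.10, but it shifts all genes, and relative to the median gene the value was 0.04. These values rest on 1 array per combination and do not settle the question alone. A higher Pou5f1 level with O(5R)SK, by 0.82 on the log2 scale, is present on every day and cannot be told apart from the OCT4 version itself, because no array has one without the other. An effect of the OCT4 version on selected programs such as the epithelial genes stays open and was not tested apart from that level.

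The 6 arrays can be split into 3 against 3 in 10 ways, which are too few for a share under 0.05. For the factor comparison 3 of the 10 splits, the real one included, gave at least as many genes at an unadjusted p under 0.05, with 1180 in the real split and 1391 in the highest other. Of these splits 6 part the arrays of 1 day only, and with day in the fit each rests on the factor difference of that day, so both splits with 1391 genes rest on the real difference on day 7. The other 4 part the arrays of every day and gave 1180 in the real split and 376 to 598 in the rest. For the slope difference 4 of the 10 did, with 949 in the real split and 1231 in the highest other, and among the 4 that part every day the highest other gave 1097.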
